A study of Mus musculus with 9 samples.

How the data were processed

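The authors made the deposited count matrices with Cell Ranger 6.0.1 on the mouse genome build GRCm38, and each matrix holds raw UMI counts (counts of unique molecular identifiers, 1 per captured transcript molecule) per gene and cell barcode. The authors deposited 2 other files with each matrix, one naming the barcodes and one naming the features. The untreated libraries were counted against 36530 features, of which 2 were transgenes, and the PBS and LPS libraries against 52636. Of these, 21897 genes could be matched one to one through gene identifiers, and they held 96.6% of the untreated UMIs and 92.1% of the PBS and LPS UMIs. Where 1 of 97 symbols stood for more than 1 Ensembl gene, the Ensembl identifier was used. Positions are GRCm38 coordinates from GENCODE M21.

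Barcodes were retained with at least 500 detected genes and at most 10% mitochondrial counts, and 74 doublet calls (0.736% of the passing cells) were removed per library by scrublet. The calls ran from 2 of 3218 passing cells (0.0622%) in LPS replicate 2 to 9 of 238 (3.78%) in untreated replicate 3. Doublets may therefore remain, above all in LPS replicate 2, the library with most cells. A neutrophil-like cluster of high UMI counts, cluster 28, was left out of the profile from which neutrophil RNA was estimated. Counts were scaled to 10000.0 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components, with genes of the 17 fixed gene lists left out, and values clipped at 10. A graph with 15 neighbours was clustered by the Leiden method at resolution 1 with seed 1. A cluster took the name of the marker list, of 19, with most members among its 10 genes of highest fold over the median cluster. The fold had 10 CPM added to both sides and was taken for genes detected in at least 10% of the cluster's cells. Ties went to the list with the larger share of markers at least 4-fold up, and at least 3 such markers were needed. Cluster 7, the chondrocyte-like class, held 2 markers of its own list and 2 of another among its 10 top genes, with 7 of 9 chondrocyte markers at least 4-fold up. Classes are called "like" a cell type because they rest on these transcripts alone.

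For each library and class the UMI counts were summed into 1 profile, so that the library, not the cell, was the replicate. A profile entered with at least 20 cells. No PBS or untreated library had 20 myelinating Schwann-like cells, so the 3 comparisons with this class used at least 4 cells, a choice made after the cell numbers were seen. For the same reason the test of the difference between classes used endothelial-like cells in place of the neutrophil-like cells, which were the largest other class but numbered at most 10 in a PBS library.

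Genes were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05) in 10 comparisons. In comparisons with a profile under 40000.0 UMIs, TMM factors came from genes expected at 10 or more counts in the shallowest profile, which was decided after simulated data had shown a bias. DESeq2 1.42.0 was the second tool. Where an arm held 2 libraries, leaving 1 out left an arm of 1, and the test then took the spread between libraries from the others. Each gene list with at least 5 tested members was tested with camera of limma 3.58.1, which asks whether a list moved more than the other genes, with the correlation between genes preset at 0.01. The same 22 lists were tested with an estimated correlation and with fry, which asks whether a list moved at all. Differences in class shares were tested with a two-sided exact permutation test over 24 comparisons, for which 3 libraries against 3 cannot give a p under 0.1. R 4.3.3, Python 3.11.15 and scanpy 1.11.5 were used.

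The tests, gene lists, marker lists and rule for naming genes were fixed before the data were examined, with the exceptions given here. The rule named, among genes with adjusted p under 0.05, mean CPM (each count divided by the library total and scaled to 1e6) of at least 20 and no overlap between the groups, the 10 highest and 10 lowest log2 fold changes in the main comparison and 5 and 5 in the others. Predicted and unnamed genes were left out. It also named up to 4 called members of each fixed list with the lowest adjusted p, and a fixed set in the main comparison (among them Gfap, Sox10, S100b, Scn7a, Mbp, Tlr4, Cd14, Il6, Cxcl1, Ccl2, Tnf and Il1b). A few genes that the rule named are not reported, and no other genes took their place. Where fewer than 3 genes passed, it named the 5 with the lowest p.

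The fixed lists were NF-kB feedback and target genes, chemokines, cytokines, interferon response, TLR and cytokine receptors and adaptors, JAK-STAT feedback and IL-6-type signalling, acute phase and secreted host defence, antigen presentation, immediate early genes, heat shock genes, glucocorticoid-responsive genes, unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, repair Schwann cell and neurotrophic genes, extracellular matrix and basal lamina, and cell cycle. Log2 fold changes are printed ± standard error (SE), CPM as mean ± SD over libraries. A fold against a group with no counts is a bound computed against 3 counts over the group. With 1 to 3 counts the ratio of counts is given with its 95% interval. Shares of cells carry 95% exact Clopper-Pearson intervals, and a share of 0 the limit of 3 cells of the total. These intervals and floors cover counting error only. In simulated data of the same depths, the main comparison recovered 65 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, with 10 false calls. The endothelial-like comparison recovered 48 and 95, the comparison of PBS with untreated 72 and 99, the endothelial difference test 6 and 52, and the myelinating difference test 0 and 5. The comparison of the Schwann-like classes recovered 5 and 8 of 20.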

Results

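Single cells sorted from mouse lung were measured by droplet-based 3' RNA sequencing in 9 libraries. The mice carried a Cre recombinase driven by the Gfap promoter and a tdTomato reporter, so that cells with a history of Gfap expression, among them the glia of peripheral nerve, fluoresced red. Cells bright for tdTomato and lacking the leukocyte, epithelial and endothelial surface proteins CD45, EPCAM and CD31 were collected. The labels give 3 groups of 3 libraries each: untreated lungs, lungs taken 2 h after oropharyngeal aspiration of 50 uL PBS, the vehicle, and lungs taken 2 h after 0.2 mg/kg LPS (lipopolysaccharide, a component of the outer membrane of gram-negative bacteria) in the same volume. The mice were females of 12 to 16 weeks. The series asks how the non-myelinating Schwann cells of the lung, glia that ensheathe small axons without forming myelin, take part in inflammation.

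The untreated libraries held 2833183, 1817603 and 977211 UMIs in 853, 698 and 299 barcodes. The PBS libraries held 5579842, 5931996 and 16683301 UMIs in 872, 879 and 2195 barcodes. The LPS libraries held 2131401, 25738889 and 8131247 UMIs in 1985, 3745 and 1226 barcodes. LPS replicate 1 was shallow, with a median of 721 UMIs per barcode against 5169 and 5768 in the other LPS libraries, and 63.8% of its barcodes were removed, 1265 of them for having fewer than 500 genes. Of 12752 barcodes, 9974 cells were retained in 30 clusters, 1549 from untreated, 3460 from PBS and 4965 from LPS libraries. The labels do not say whether replicates are separate animals, so the p-values measure the spread between these libraries.

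Non-myelinating Schwann-like cells made up 90.4% ± 4.18 (SD, n = 3) of the untreated cells, 63.1% ± 17.9 of the PBS cells and 43.3% ± 14.5 of the LPS cells. Neutrophil-like cells, phagocytes that enter inflamed tissue early, made up 19.05% ± 13.7 of the LPS cells against 0.303% ± 0.270 of the PBS cells, and the libraries of the 2 groups did not overlap. The per-library shares after LPS were 4.52% (95% exact Clopper-Pearson interval 3.11 to 6.32), 31.8% (30.2 to 33.4) and 20.8% (18.4 to 23.4). PBS replicate 2 held none, which allows a share of up to 0.393%. Chondrocyte-like cells, the matrix-making cells of airway cartilage, made up 2.66% ± 1.04 of the LPS cells and 7.16% ± 2.77 of the PBS cells, again without overlap. Each of these 2 differences gave p = 0.1 in the two-sided exact permutation test, the smallest value that 3 libraries against 3 allow, so no share could pass 0.05. The share of non-myelinating Schwann-like cells overlapped between LPS and PBS (exact permutation p = 0.2).

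For the other classes the LPS and PBS shares overlapped, with exact permutation p from 0.2 to 0.9. They were 4.08% ± 3.58 against 8.41% ± 7.53 for endothelial-like, 8.88% ± 5.95 against 4.40% ± 2.67 for epithelial-like, 4.43% ± 3.14 against 5.32% ± 2.12 for fibroblast-like and 9.39% ± 15.0 against 1.49% ± 1.01 for smooth muscle-like cells. The smooth muscle-like share was 26.7%, 0.995% and 0.480% in the LPS libraries, and without LPS replicate 1 the difference turned to −0.753 percentage points. Myelinating Schwann-like cells, which wrap large axons in myelin, made up 1.16% ± 1.26 after LPS and 0.475% ± 0.454 after PBS. In the PBS libraries the non-myelinating share lay below that of every untreated library (exact permutation p = 0.1). Chondrocyte-like cells (7.16% against 1.74% ± 1.496), fibroblast-like cells (5.32% against 1.47% ± 1.30) and T or NK cell-like cells (3.41% ± 1.68 against 0%) lay above every untreated library at the same p. The 3 untreated libraries held no macrophage-like, T or NK cell-like or epithelial-like cell, which allows shares of up to 0.400%, 0.526% and 1.31%. The sort sets these shares in part.

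**Figure D1:**
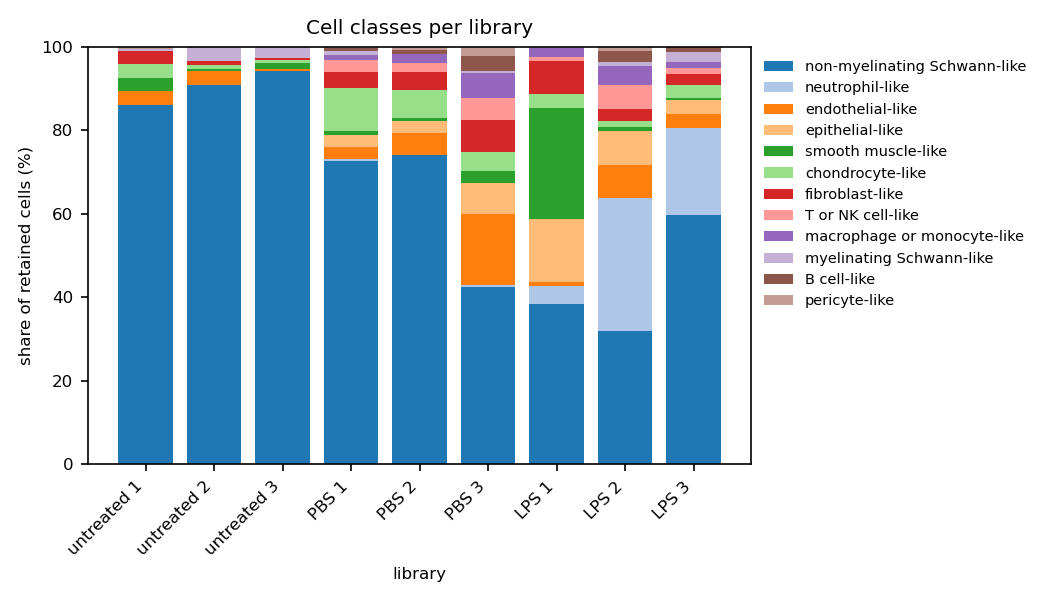
Stacked bars give the share of retained cells (%) that each marker-defined class took in each of the 9 libraries, 3 per group. Neutrophil-like cells were 4.52%, 31.8% and 20.8% of the LPS libraries.

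The main comparison asks what LPS changed in non-myelinating Schwann-like cells 2 h after aspiration, relative to PBS. Genes for chemokines that attract neutrophils and monocytes showed some of the largest changes. Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), a neutrophil attractant, was higher by 8.68 ± 0.57 on the log2 scale (SE, n = 3 libraries per group), at 5417 ± 2748 against 13.0 ± 3.40 CPM. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), a monocyte attractant, was higher by 7.95 ± 0.60, at 3628 ± 1305 against 14.1 ± 9.80 CPM. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced attractant of T cells, was higher by 6.56 ± 0.74, at 5335 ± 971 against 56.5 ± 46.4 CPM. Acod1, which makes the antimicrobial metabolite itaconate, rose by 9.01 ± 0.65, and Ptx3, a soluble pattern recognition protein, rose by 8.50 ± 0.82. Adamts4, a protease that cleaves matrix proteoglycans, rose by 6.39 ± 0.86. Lif, a cytokine of the IL-6 family, had 3 counts over the PBS libraries and was 421-fold (95% counting interval 144 to 2043) higher. The neutrophil calprotectin genes S100a9 and S100a8 had 2 PBS counts each and were 1021-fold (95% counting interval 282 to 8439.9) and 781-fold (95% counting interval 216 to 6459) higher. The share of neutrophil RNA in the non-myelinating class, estimated from 9 markers that include these 2, was 0.161%, 0.217% and 0.218% after LPS and 0% after PBS. That RNA accounted for 2.56% of the rise of Cxcl2 and 3.17% of that of Acod1.

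Among the called genes that met the naming rule, the lowest fold changes belonged to Ctgf and Axin2. Ctgf (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), a matricellular target of YAP signalling, fell by 2.35 ± 0.27 on the log2 scale (35.3 ± 8.82 against 164 ± 53.6 CPM). Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback inhibitor of Wnt signalling, fell by 2.00 ± 0.20 (7.58 ± 1.84 against 33.0 ± 4.43 CPM). Pax3, a transcription factor of the neural crest lineage from which Schwann cells arise, was lower (−1.51 ± 0.24), as were Flrt1 (−1.72), Cdc42ep3 (−1.38), Gas1 (−1.28), Mrgprf (−1.24), Tmcc3 (−1.23) and the long non-coding RNA Dubr (−1.22). In all, edgeR called 1945 of 12093 genes, 1364 higher and 581 lower after LPS, from profiles of 496053 to 6313212 UMIs. Cluster 4 held 0.178%, 2.65% and 3.06% of this class after PBS and 12.5%, 45.6% and 31.4% after LPS, so the cells compared lay in part in different clusters. The 3 LPS libraries did not overlap the 3 PBS libraries for 34.2% of the tested genes, where chance gives 10%, and for 1849 of the calls. With the replicate number as a block the count was 1587 (1189 higher, 398 lower), although the numbers do not pair the libraries, whose same-number correlations were 0.0468, −0.0501 and −0.0880. Without PBS replicate 1 the count was 1292 (992 higher, 300 lower). Upper-quartile scaling gave 2292 calls, 1053 higher and 1239 lower, and shifted the log2 fold changes by a median of −0.131 (by −0.119 in endothelial-like and −0.123 in fibroblast-like cells), so that changes smaller than this depend on the scaling.

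**Figure D2:**
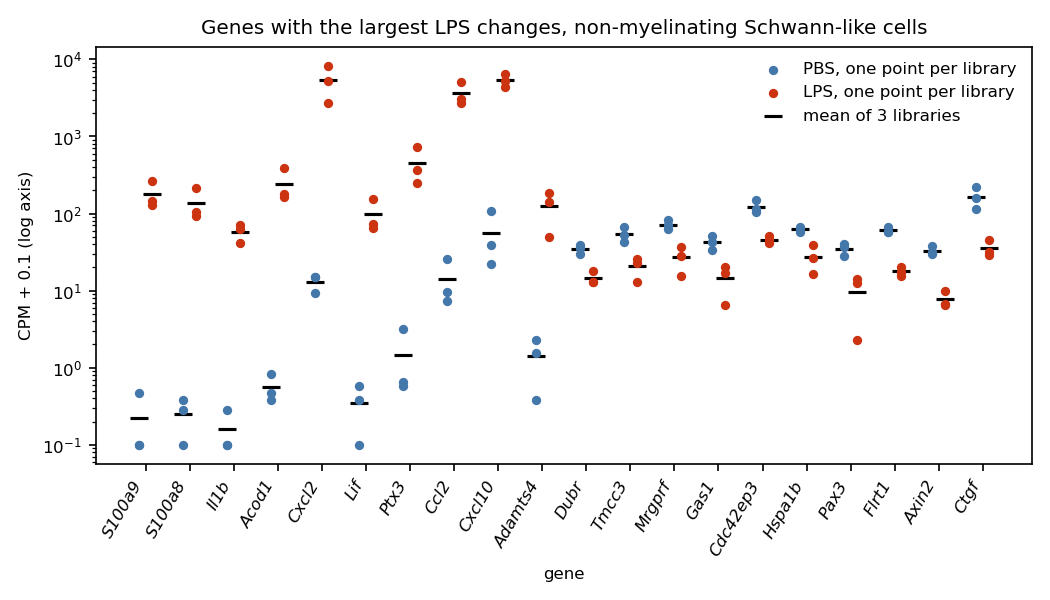
CPM plus 0.1 on a log axis in non-myelinating Schwann-like cells, one point per library and a bar for the mean of 3 libraries. The genes are those with the largest changes among the called genes that met the naming rule. Cxcl2 stood at a mean of 5417 CPM after LPS and 13.0 after PBS, and Ctgf at 35.3 and 164 CPM.

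Most tested NF-kB, chemokine, cytokine and interferon response genes were higher in the non-myelinating class, although with an estimated correlation no list passed (lowest adjusted p = 0.0703). Of 19 tested NF-kB feedback and target genes, 18 were higher and none lower (18 adjusted over the list alone), among them Nfkbia, the inhibitor that NF-kB induces against itself (2.81 ± 0.15, 2676 ± 453 against 382 ± 20.3 CPM), Birc3 (2.84 ± 0.15), Relb (2.94 ± 0.17) and the adhesion molecule Vcam1 (2.99 ± 0.16). Of 9 chemokines, 8 were higher (8 adjusted over the list alone), with Cxcl16 at 4.16 ± 0.32, Cxcl1 at 2.95 ± 0.31, and Ccl3 and Cxcl3, absent from the PBS profiles, at least 36.2-fold and at least 22.3-fold higher. Of 10 cytokines, 8 were higher (8 adjusted over the list alone), among them Il6 (6.30 ± 0.40, 31.3 ± 5.57 against 0.338 ± 0.373 CPM), the alarmin Il33 (4.53 ± 0.47) and the macrophage growth factor Csf1 (2.91 ± 0.24), while Csf2 and Il34 were not called. Il1b, with 1 PBS count, was 718-fold (95% counting interval 128 to 28403) higher. The estimated neutrophil RNA accounted for at least 50% of the rise of 4 of these 16 chemokine and cytokine genes, Ccl3 (59.9%), Cxcl3 (159%), Il1b (90.6%) and Il1rn. Tnf had too few counts to be tested, with 1, 11 and 12 after LPS and 0 in each PBS library. All 31 interferon response genes were higher (31 adjusted over the list alone), with Ifit3 at 3.44 ± 0.15 (1462 ± 109 against 135 ± 21.6 CPM), Ifit1 at 4.09 ± 0.20, Ifit3b at 3.04 ± 0.15 and the GTPase Iigp1 at 3.59 ± 0.17.

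Of 22 receptors and adaptors for bacterial products and cytokines, 10 were higher and none lower (12 adjusted over the list alone), with Tlr2, a receptor for bacterial lipoproteins, at 4.26 ± 0.21 and the adaptor Myd88 at 1.51 ± 0.16, Irak2 at 2.24 ± 0.26 and the LPS co-receptor Cd14 at 2.31 ± 0.26 (35.1 ± 7.88 against 6.53 ± 2.40 CPM), of whose rise neutrophil RNA accounted for 55.3%. The LPS receptor Tlr4 was not called (−0.06 ± 0.17, adjusted p = 0.897, 29.3 ± 5.07 against 32.4 ± 5.03 CPM). Of 13 genes of JAK-STAT feedback and IL-6-type signalling, 9 were higher (10 adjusted over the list alone), such as Stat3 (1.15 ± 0.14), Cebpb (1.64 ± 0.15), Socs2 (2.01 ± 0.19) and Il4ra (1.84 ± 0.18). Of 12 acute phase and host defence genes, 9 were higher (10 adjusted over the list alone), with ceruloplasmin, Cp, at 1.99 ± 0.17, the zinc transporter Slc39a14 at 2.16 ± 0.20, Serpina3n at 1.94 ± 0.20 and the siderophore-binding Lcn2, with 1 PBS count, 318-fold (95% counting interval 56.7 to 12618) higher. Of 12 antigen presentation genes, 9 were higher (9 adjusted over the list alone), with Tap1, a peptide transporter, at 2.57 ± 0.18, H2-Q4 at 2.34 ± 0.15, Psmb8 at 1.43 ± 0.13 and H2-K1 at 1.33 ± 0.12. Of 12 glucocorticoid-responsive genes, 6 were higher (8 adjusted over the list alone), with the metal-binding metallothioneins Mt1 at 3.49 ± 0.21 (23965 ± 665 against 2135 ± 578 CPM) and Mt2 at 4.18 ± 0.23, Errfi1 at 2.11 ± 0.25 and Sgk1 at 1.24 ± 0.17.

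Other groups moved less evenly. Of 23 immediate early genes, 4 were higher and none lower (8 adjusted over the list alone), namely Myc (1.61 ± 0.14), Fosl1 (4.14 ± 0.39), Maff (1.68 ± 0.18) and Fosl2 (1.48 ± 0.16). Of 11 genes of glycolysis and hypoxia, 4 were higher (5 adjusted over the list alone), Hk2, the first enzyme of glycolysis, by 2.65 ± 0.17, with Ldha (0.65), Hif1a (0.58) and Vegfa (1.08). Of 12 heat shock genes, 3 were higher and 3 lower (the same counts adjusted over the list alone), among them Hsp90aa1 (0.72 ± 0.16) and Bag3 (0.49) higher and Hspa1b (−1.42 ± 0.22) and Hspa1a (−0.80 ± 0.17) lower. Of 19 genes of cholesterol synthesis, 3 were higher and 2 lower (4 and 2 adjusted over the list alone), with Insig1 (0.80) higher and Mvk (−0.86) and Dhcr7 (−0.95) lower. Of 14 genes of the unfolded protein response, 3 were higher (3 adjusted over the list alone), Atf4 (0.57), Herpud1 (0.50) and Xbp1 (0.45). Of 10 repair Schwann cell and neurotrophic genes, 1 was higher (1 adjusted over the list alone), the neurotrophic factor Gdnf (2.16 ± 0.39). Of 18 extracellular matrix and basal lamina genes, 1 was higher and 3 lower (1 and 6 adjusted over the list alone), Loxl2 (0.79 ± 0.15) against Col5a3 (−0.48), Nid1 (−0.41) and Postn (−0.47). None of 6 cell cycle genes was called by edgeR (0 adjusted over the list alone).

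Some of these smaller changes lost their call when 1 library was left out, which also leaves fewer libraries to test. The calls of Bag3, Atf4, Herpud1, Xbp1, Ldha, Hif1a, Vegfa, Mvk, Dhcr7, Col5a3, Nid1 and Postn were lost when particular libraries were left out. The highest adjusted p was 0.0882 for Bag3 (lost without PBS replicate 1, PBS replicate 2 or LPS replicate 2), 0.0622 for Atf4 (PBS replicate 2), 0.104 for Herpud1 (each PBS replicate or LPS replicate 3) and 0.184 for Xbp1 (any library but LPS replicate 1). It was 0.0589 for Ldha (PBS replicate 1 or 2), 0.155 for Hif1a (PBS replicate 2 or LPS replicate 2), 0.0934 for Vegfa (PBS replicate 1 or 3, LPS replicate 2 or 3), 0.0676 for Mvk (LPS replicate 3) and 0.142 for Dhcr7 (PBS replicate 1 or LPS replicate 2). It was 0.107 for Col5a3 (PBS replicate 1 or 2, LPS replicate 3), and 0.142 for Nid1 and 0.122 for Postn (any library but LPS replicate 2). With Gfap, given below, 13 of the 79 named calls in this class were lost so, and the other 66, among them every inflammatory gene named above, were kept without each library in turn.

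Some genes that define Schwann cells were called and others were not. Among 19 non-myelinating Schwann markers, 2 were higher and 4 lower (2 and 6 adjusted over the list alone). Over all tested genes edgeR called 1945 of 12093, so calls were not rarer among these markers. Sox10 (ENSMUSG00000033006, chromosome 15, 79154908 to 79165240), the transcription factor that maintains Schwann cell identity, was lower by 0.92 ± 0.13 on the log2 scale (209.8 ± 16.2 against 401 ± 56.3 CPM), and Gfra3, Gfra2 and Foxd3 were lower by 0.62, 0.58 and 0.51. Gfap, the glial intermediate filament, was higher by 0.96 ± 0.26 (330.4 ± 79.1 against 173 ± 54.0 CPM, adjusted p = 0.0476), and the neurotrophin receptor Ngfr by 0.78. The Gfap call was lost without PBS replicate 2 (adjusted p = 0.0785) and without LPS replicate 1 (0.0627), 2 (0.200) or 3 (0.112). S100b (−0.17 ± 0.12, adjusted p = 0.349), Scn7a (0.02 ± 0.13, 0.965) and the myelin gene Mbp (0.19 ± 0.16, 0.467) were not called. Of 14 tested myelinating Schwann markers 1 was lower, Sox10 (1 adjusted over the list alone).

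Markers of other cell types moved as well. Marker genes outside the naming rule are named here after their values were seen. Of 5 tested neutrophil markers, 4 were higher (4 adjusted over the list alone, with G0s2 lower), S100a8, S100a9, Retnlg and Clec4d. Of 4 macrophage markers, Tyrobp (by 5.11) and Fcer1g were higher, and neutrophil RNA accounted for 76.8% and 121% of their rise in CPM. Of 6 fibroblast markers, Col3a1 and Col1a1 were lower by 0.98 and 0.52, and of 2 pericyte markers Postn was lower. No tested marker of neurons (3), perineurial cells (3), smooth muscle (3), epithelium (5), endothelium (1), chondrocytes (1), melanocytes (1) or erythroid cells (1) was called by edgeR, and none was tested for mesothelium, T or NK cells, B cells, mast cells or platelets. In LPS replicate 2, Ccl2 was detected in 57.1% of 1027 non-myelinating Schwann-like cells (95% exact interval 54.0 to 60.1), at a median of 5993 UMIs per cell, and in 6.90% of 87 B cell-like cells (2.57 to 14.4), at a median of 4516. In the same library Cxcl1 was detected in 63.7% against 10.3%, Cxcl10 in 59.0% against 6.90%, Il6 in 10.6% against 1.15% and Tlr4 in 12.7% against 1.15%. Il1b (24.1% against 28.7%, exact interval 19.5 to 39.4) did not exceed the B cell-like share. Cd14 (12.1% against 11.5%, exact interval 5.65 to 20.1) lay within its interval. The B cell-like profile of this library held an estimated 6.36% of non-myelinating Schwann RNA, so it is not a clean background. For Il1b and Cd14 this comparison therefore cannot separate expression in non-myelinating cells from background.

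Camera called 13 of the 22 lists, 12 upward and 1 downward, against the other genes. The lowest adjusted p were 1.18e-33 for interferon response, 7.86e-21 for NF-kB targets, 9.45e-11 for cytokines, 3.41e-10 for chemokines and 1.84e-09 for acute phase genes. With an estimated correlation these gave adjusted p = 0.0718, 0.0707, 0.0703, 0.0864 and 0.0707, and no list passed. The other upward calls, with the value by an estimated correlation second, were antigen presentation (adjusted p = 1.29e-07 and 0.0933), glucocorticoid-responsive genes (2.19e-07 and 0.145), JAK-STAT feedback (9.26e-07 and 0.0864), neutrophil markers (6.57e-06 and 0.0864), receptors and adaptors (1.06e-05 and 0.205), immediate early genes (0.00332 and 0.601) and glycolysis (0.00512 and 0.0933). The downward call was extracellular matrix (0.0227 and 0.614). Fry, which asks whether a list moved at all and not whether it moved more than other genes, called 11 of them, not immediate early genes (adjusted p = 0.126) or extracellular matrix (0.174). Without LPS replicate 1 the immediate early list did not pass by camera (adjusted p = 0.0628). Heat shock genes (0.820), unfolded protein response (0.475), cholesterol synthesis (0.475), repair genes (0.521), cell cycle (0.521), non-myelinating markers (0.300), myelinating markers (0.521), fibroblast markers (0.192) and epithelial markers (0.233) did not pass by camera. Without PBS replicate 3 epithelial markers (0.0156) and cholesterol synthesis (0.0270) passed upward. For heat shock genes the median log2 change was 0.12, the mean −0.01 and the direction of the test upward. With the replicate number as a block the 12 upward lists passed again, with 1 more that was too small to test without the block. Extracellular matrix did not pass with it (adjusted p = 0.0522), nor without PBS replicate 1 (0.0709), LPS replicate 1 (0.0679) or LPS replicate 3 (0.173).

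**Figure D3:**
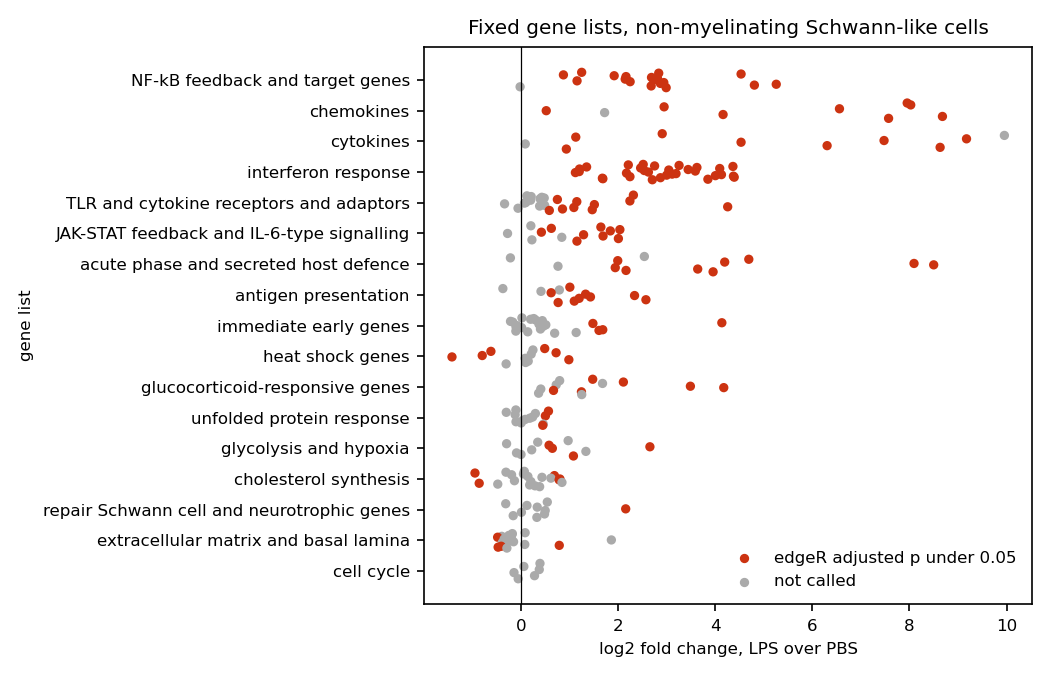
Log2 fold changes, LPS over PBS, of each tested member of the 17 fixed lists in non-myelinating Schwann-like cells, with 3 libraries per group and red points for an edgeR adjusted p under 0.05. All 31 interferon response genes lie right of 0 in red, and values of genes with 3 or fewer PBS counts depend on the prior count of the fit.

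The same contrast in myelinating Schwann-like cells asks whether the other Schwann cell class responded. Only Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), a metallothionein, passed the test, higher by 2.17 ± 0.20 on the log2 scale (SE, n = 2 libraries per group), at 20293 ± 2749.6 against 4509 ± 639 CPM (adjusted p = 0.000561). The next genes by p did not pass: Mt2 (2.81 ± 0.48, adjusted p = 0.0957), Isg15 (at least 6.33-fold, 0.0957), Erdr1 (−3.98 ± 0.76, 0.0957) and Klf4 (−2.27 ± 0.44, 0.0957). Of 7 tested glucocorticoid-responsive genes, 1 was higher, Mt1 (4 adjusted over the list alone), and of 3 interferon response genes none (2 adjusted over the list alone). Between 7 and 32 cells per library gave profiles of 29168 to 113350 UMIs, which allowed 1178 genes to be tested, 107 of them with an unadjusted p under 0.05. The count was 30 without PBS replicate 1, 23 without PBS replicate 3, 4 without LPS replicate 2 and 14 without LPS replicate 3, each from a fit with 1 library in an arm, which is assumed to vary like the others.

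A test of the difference between the 2 Schwann-like classes in their LPS effect called 11 of 11284 genes. Of these, 3 had a higher effect in myelinating and 8 in non-myelinating cells. Effects are signed log2 changes, so a fall in either class counts as a higher effect in the other. With TMM factors from all tested genes 10 passed, 6 with a higher effect in myelinating and 4 in non-myelinating cells. The balance of directions therefore depended on the scaling. Klf4 (adjusted p = 0.298) and Mt2 (0.219), given below, did not pass with these factors, and the other 6 named genes did. Gadd45b, a stress-induced NF-kB target, differed by −3.21 ± 0.40 on the log2 scale (SE, n = 2 libraries per group): it stood at 699.8 CPM after LPS and 812 after PBS in myelinating, and at 448 and 55.0 in non-myelinating cells. Cxcl10 differed by −7.60 ± 0.81 (103 and 124 CPM in myelinating, 5039.6 and 32.6 in non-myelinating cells), and Nfkbia by −1.99 ± 0.36 (1106 and 716 against 2589 and 424). Mt1 differed by −1.48 ± 0.25, Mt2 by −1.48 ± 0.32 and Klf4 by −1.75 ± 0.41, and Cebpd by 2.45 ± 0.60 and Fxyd6 by 3.22 ± 0.49 the other way. With DESeq2 Gadd45b (adjusted p = 0.0367) and Cxcl10 (1.40e-11) passed. Mt1 (0.0674), Nfkbia (0.815) and the rest of these 8 named genes did not. Of these 8 named genes, only Gadd45b kept its call without each library in turn, although each such fit leaves 1 library in an arm, which is assumed to vary like the others. With each cell thinned to 1000 UMIs none of the 8 passed: Gadd45b stood at −2.41 (adjusted p = 0.910), Nfkbia at −2.32 (0.0517) and Mt1 at −1.46 (0.0682). Fxyd6 fell to 1.34 and Cebpd to 1.04, while Cxcl10 stood at −7.96, Klf4 at −1.57 and Mt2 at −1.56. Without PBS replicate 3 the adjusted p was 0.142 for Cxcl10, 0.719 for Nfkbia and 1 for Fxyd6, whose difference fell to 1.27. Mt1 was lost without LPS replicate 2 (adjusted p = 0.0901), Mt2 without PBS replicate 1 (difference −0.14), LPS replicate 2 or LPS replicate 3, Nfkbia also without LPS replicate 3 (0.0796), Cebpd without PBS replicate 1 (0.0783), PBS replicate 3 or LPS replicate 2, and Klf4 without PBS replicate 3, LPS replicate 2 or LPS replicate 3. The count was 21 without PBS replicate 1, 5 without PBS replicate 3 or LPS replicate 2, and 6 without LPS replicate 3.

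In the other sorted classes, LPS was compared with PBS to see which changes of the Schwann-like cells other lung cells also showed. In endothelial-like cells (n = 2 LPS and 3 PBS libraries), the chemokine gene Cxcl10 was higher by 7.87 ± 0.30 on the log2 scale (1475 ± 7.85 against 3.92 ± 3.54 CPM) and Icam1 (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), an adhesion molecule for leukocytes, by 3.44 ± 0.19 (1548 ± 101 against 140.5 ± 24.9 CPM). Il1b and Acod1, absent from the PBS profiles, were at least 515-fold and at least 106-fold higher, and Cxcl2, S100a9 and S100a8, with 1 PBS count each, 2574-fold (95% counting interval 461 to 101733), 1583-fold (95% counting interval 284 to 62579) and 1126-fold (95% counting interval 202 to 44542). Mt1 (7.16 ± 0.30) and Mt2 (7.13 ± 0.41) and the glycolytic regulator Pfkfb3 (3.62 ± 0.28) also rose. Cyp26b1, which degrades retinoic acid, was lower (−3.23 ± 0.37), as were Hey1, a target of Notch signalling (−2.83 ± 0.33), Hebp1 (−2.84 ± 0.66, lost without LPS replicate 2 at an adjusted p of 0.214) and Tox3 (−1.91 ± 0.32). Erdr1 was lower (−5.98 ± 0.78), a call lost without LPS replicate 2 (adjusted p = 0.0983). Of 16 NF-kB genes 14 were higher (15 adjusted over the list alone), such as Tnfaip3 (4.09 ± 0.32), Nfkbia (2.29 ± 0.18) and Nfkbiz (1.89 ± 0.22). Of 28 interferon response genes 10 were higher (18 adjusted over the list alone), such as Ifit2 (4.05 ± 0.37) and Rsad2 (5.48 ± 0.61), while none of 13 antigen presentation genes was called by edgeR (0 adjusted over the list alone). Of 11 JAK-STAT genes 8 were higher and 1 lower (the same counts adjusted over the list alone), and of 19 immediate early genes 7 were higher and 1 lower (11 and 1 adjusted over the list alone).

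The endothelial-like comparison called 306 of 4051 genes, 251 higher and 55 lower, with 32.8% of the tested genes separated between the groups, where chance gives 20% for 2 libraries against 3. Neutrophil markers were higher for 3 of 3 and macrophage markers for 2 of 3, and the estimated neutrophil RNA was 1.19% and 1.35% of the 2 LPS profiles. S100a8 and S100a9 stood at 0.828% and 0.946% of their level in neutrophil-like cells in LPS replicate 2. In LPS replicate 3 they stood at 1.35% and 0.799%. Neutrophil RNA can account for values of this size, and its part in the rise of Il1b, Acod1 and Cxcl2 is not given here. With that RNA subtracted, 36 of the 40 named calls could still be tested, and all 36 were kept. Subtraction can push a gene below the filter on low counts, so the named calls that could not be tested stay open. Of the 40 named calls 15 were lost without at least 1 library, Hebp1 and Erdr1 among them. With the replicate number as a block the count was 146 (134 higher, 12 lower). The count was 149 without PBS replicate 3, 129 without LPS replicate 2 and 460 without LPS replicate 3, the last 2 with 1 LPS library, which is assumed to vary like the PBS libraries.

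In fibroblast-like cells (n = 3 per group), Ccl2 was higher by 9.43 ± 0.74 on the log2 scale (2379 ± 1119 against 1.68 ± 2.90 CPM), Cxcl2 by 8.05 ± 0.56, Cxcl10 by 7.06 ± 1.06, Cxcl1 by 4.73 ± 0.39 and the monocyte attractant Ccl7 by 6.52 ± 0.53. Ptx3 and the antiviral Rsad2, with 1 PBS count each, were 271-fold (95% counting interval 48.0 to 10739.9) and 357-fold (95% counting interval 63.6 to 14170.1) higher. Timp1, an inhibitor of matrix proteases, rose by 4.11 ± 0.43, Ch25h by 4.07 ± 0.44, Serpina3n by 2.96 ± 0.32 and Mt1 by 4.62 ± 0.62, and the extracellular protein Spon2 fell by 2.11 ± 0.28. Of 17 NF-kB genes 15 were higher (17 adjusted over the list alone), such as Tnfaip3 (4.72 ± 0.37), Sod2 (3.24 ± 0.37) and Birc3 (3.18 ± 0.37). Of 9 chemokines 7 were higher (7 adjusted over the list alone), of 20 interferon response genes 14 (18 adjusted over the list alone), such as Isg15 (4.78 ± 0.31) and Ifit1 (6.78 ± 0.57), and of 8 antigen presentation genes 3 (3 adjusted over the list alone), with H2-Q4 at 2.60 ± 0.31. None of 16 matrix genes was called by edgeR. Of the 2 clusters of this class, cluster 14 held 16, 19 and 40 PBS and 51, 29 and 14 LPS cells, and cluster 12 held 14, 14 and 109 against 6, 56 and 13. The comparison called 208 of 4281 genes, 188 higher and 20 lower, with 21.6% of the tested genes separated. The estimated neutrophil RNA was 0%, 1.35% and 2.76% of the LPS profiles. Of the 41 named calls 16 were lost without at least 1 library, 15 of them without LPS replicate 3 and 14 without LPS replicate 2, but none of the genes given here with a value. With the replicate number as a block the count was 193. It was 313 without LPS replicate 1, 96 without LPS replicate 2 and 89 without LPS replicate 3.

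In chondrocyte-like cells (n = 3 per group), Isg15, an interferon-induced ubiquitin-like protein, was higher by 5.86 ± 0.36 on the log2 scale (148 ± 52.1 against 2.72 ± 0.530 CPM), Ccl2 by 4.83 ± 0.55, Gbp7 by 3.71 ± 0.35 and the stress-induced Ddit4 by 2.37 ± 0.26. Gbp5 and Stx11, with 2 PBS counts each, were 204-fold (95% counting interval 55.5 to 1694) and 47.2-fold (95% counting interval 12.2 to 404) higher, and Erdr1 was lower by 5.08 ± 0.57. Of 15 NF-kB genes 11 were higher (14 adjusted over the list alone), such as Sod2 (2.48 ± 0.25), Nfkbia (2.11 ± 0.27) and Tnfaip3 (3.31 ± 0.46), and of 10 interferon response genes 8 (10 adjusted over the list alone), such as Irf9 (2.20 ± 0.33). Of 7 antigen presentation genes 5 were higher (7 adjusted over the list alone). Of 12 heat shock genes 3 were lower (4 adjusted over the list alone), Hspa1a (−1.58 ± 0.28), Dnajb1 (−1.86 ± 0.35) and Hspa1b (−2.02 ± 0.45), and of 22 immediate early genes 3 (1 higher and 7 lower adjusted over the list alone), Atf3 (−1.48 ± 0.27), Klf4 (−1.28 ± 0.27) and Nr4a1 (−1.24 ± 0.27). The calls of all 3 heat shock and all 3 immediate early genes were lost without LPS replicate 2, with adjusted p from 0.0518 for Atf3 to 0.183 for Hspa1b, and also without PBS replicate 1 except for Hspa1a. Klf4 was lost without PBS replicate 3 too (0.112), Nr4a1 without any library but LPS replicate 3, and Hspa1b without any but PBS replicate 3. In all, 23 of the 35 named calls were lost without at least 1 library, 19 of them without LPS replicate 2 and 13 without PBS replicate 1. The comparison called 146 of 6955 genes, 108 higher and 38 lower, with 18.6% of the tested genes separated and 1 of 2 neutrophil markers higher. With the replicate number as a block the count was 100. It was 66 without PBS replicate 1, 97 without PBS replicate 2, 45 without LPS replicate 2 and 257 without LPS replicate 3.

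In epithelial-like cells (n = 3 per group), Cxcl2 was higher by 9.46 ± 0.77 on the log2 scale (1002 ± 589 against 0.569 ± 0.986 CPM), the metalloreductase Steap4 by 5.83 ± 0.41, Cd14 by 3.68 ± 0.34 (1141 ± 112 against 93.6 ± 36.7 CPM) and Hk2 by 2.05 ± 0.22. S100a9 and Il1rn, which encodes the antagonist of the IL-1 receptor, were absent from the PBS profiles and at least 530.0-fold and at least 32.0-fold higher, and Il1b, with 1 PBS count, 705-fold (95% counting interval 126 to 27859). Of 17 NF-kB genes 13 were higher (15 adjusted over the list alone), such as Tnfaip3 (3.76 ± 0.35), Tnip3 (4.47 ± 0.49) and Nfkbiz (2.39 ± 0.27). Of 7 chemokines 6 were higher (7 adjusted over the list alone), of 7 cytokines 4 (5 adjusted over the list alone) and of 16 interferon response genes 4 (11 adjusted over the list alone). None of 12 antigen presentation genes was called by edgeR (4 adjusted over the list alone). Myb was lower by 3.50 ± 0.46, a call lost without PBS replicate 2 (adjusted p = 0.0570) and PBS replicate 3 (0.173). Of the 41 named calls 30 were lost without at least 1 library, 28 of them without PBS replicate 2, 24 without PBS replicate 3 and 21 without PBS replicate 1. The other genes given here with a value were not, but Il1rn could be tested without 3 of the 6 libraries alone. With at least 1000 genes per cell 2 genes passed, and of the named calls Steap4 was kept and the other 40 were lost. The clusters of this class were unevenly filled, so that a change of cell subtypes was not separated from a change within cells. Cluster 21 (Sftpa1 and Sftpc among its top genes) held 0, 0 and 1 PBS and 15, 77 and 11 LPS cells. Cluster 17 (Sftpc) held 9, 7 and 77 against 0, 76 and 8, and cluster 18 (Bpifa1 and Scgb1a1) 8, 1 and 10 against 74, 56 and 10. The comparison called 130 of 6453 genes, 125 higher and 5 lower, with 24.2% of the tested genes separated and 2 of 2 neutrophil markers higher. The estimated neutrophil RNA was 0.218%, 0.982% and 0.305% of the LPS profiles, and its part in the rise of S100a9, Il1rn and Il1b is not given here. S100a9 stood at 719 CPM in LPS replicate 2, against 73268 CPM in the neutrophil-like cells of that library. With that RNA subtracted, 37 of the 41 named calls could still be tested, and 34 were kept. The calls that subtraction left with too few counts to test stay open. With the replicate number as a block the count was 77. It was 63 without PBS replicate 1, 24 without PBS replicate 2, 29 without PBS replicate 3, 82 without LPS replicate 2 and 86 without LPS replicate 3.

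**Figure D4:**
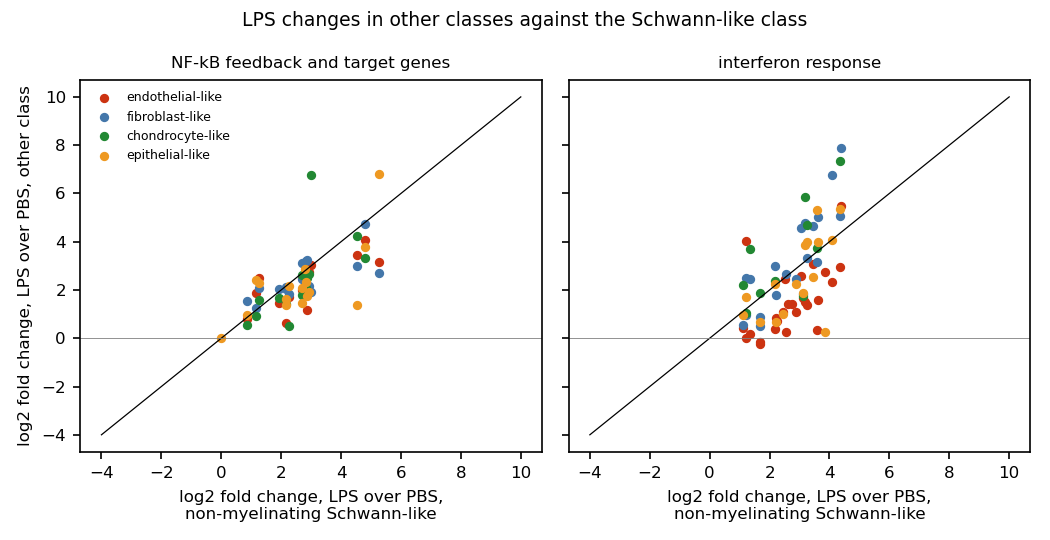
Log2 fold change, LPS over PBS, of NF-kB and interferon response genes in 4 other classes against the same value in non-myelinating Schwann-like cells, one point per gene and class, from 2 or 3 LPS and 3 PBS libraries. The line marks equal values, and Iigp1 is among the interferon genes that lie below it for endothelial-like cells, at 1118 CPM after LPS and 853 CPM after PBS.

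Whether the LPS effect itself differed between endothelial-like and non-myelinating Schwann-like cells was tested directly (n = 2 LPS and 3 PBS libraries). Of 13189 genes 375 passed, 197 with the higher effect in endothelial-like and 178 in non-myelinating cells. Effects are signed log2 changes, so a fall in either class counts as a higher effect in the other. Interferon response genes had the higher effect in the non-myelinating class for 17 of 33 members and in the endothelial-like class for 1 (24 and 1 adjusted over the list alone). Iigp1, a GTPase against intracellular pathogens, differed by −3.02 ± 0.25 on the log2 scale: it stood at 1118 CPM after LPS and 853 after PBS in endothelial-like cells, and at 669 and 58.8 in non-myelinating cells. Gbp2 (−1.85 ± 0.27) and Igtp (−2.01 ± 0.30) differed the same way and Ifit2 (2.66 ± 0.41) the other way. Of 13 antigen presentation genes 6 had the higher effect in the non-myelinating class (7 adjusted over the list alone), among them H2-Q4 (−1.93 ± 0.26). Mt1 had the higher effect in endothelial-like cells (3.52 ± 0.32), rising from 13.9 to 2553 CPM there and from 2299 to 25150.4 in non-myelinating cells, as did Mt2 (2.79 ± 0.43) and Pfkfb3 (2.86 ± 0.36). Vegfa (−1.89 ± 0.35), Plaur (−3.39 ± 0.37) and Slfn5 (−3.63 ± 0.31) had the higher effect in non-myelinating cells, and G0s2 (4.69 ± 0.40) in endothelial-like cells. These 12 of the 43 named genes kept their call without each library in turn, where leaving out an LPS library leaves 1, which is assumed to vary like the others. G0s2 is a neutrophil marker, and its call was lost with neutrophil RNA subtracted (difference 3.64, adjusted p = 0.333). That RNA was 1.19% and 1.35% of the endothelial-like and 0.217% and 0.218% of the non-myelinating LPS profiles. Of 19 non-myelinating Schwann markers, 7 had the higher effect in endothelial-like cells (10 and 1 lower adjusted over the list alone). The count was 209 without PBS replicate 2, 125 without PBS replicate 3, 143 without LPS replicate 2 and 211 without LPS replicate 3.

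Vehicle aspiration was compared with untreated lungs in non-myelinating Schwann-like cells. These groups also differ in the gene annotation, and the labels do not say whether they shared a sequencing run, so that treatment and processing cannot be separated in any value of this comparison. The cells compared also lay in different clusters: cluster 2 held 68.2%, 82.4% and 70.8% of the class in the untreated libraries and 0.533%, 0.531% and 0.857% in the PBS libraries. Cluster 0 held 1.24%, 0.579% and 1.39% against 72.6%, 58.2% and 69.0%. The heat shock genes Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) and Hspa1a, chaperones induced by stress, were lower in PBS than in untreated cells by 4.42 ± 0.13 and 3.47 ± 0.13 on the log2 scale (SE, n = 3 per group), at 68.4 ± 5.39 against 1461 ± 111 CPM and 226 ± 24.6 against 2510.5 ± 259 CPM. The AP-1 subunits Jund and Junb were lower by 1.86 ± 0.12 (1724 ± 61.4 against 6261 ± 769 CPM) and 1.28 ± 0.13, and Atf3 by 1.51 ± 0.13. Of 22 immediate early genes 20 were lower and 1 higher (21 and 1 adjusted over the list alone), and of 12 heat shock genes 7 lower and 2 higher (8 and 2 adjusted over the list alone). Of 10 antigen presentation genes 8 were lower and 1 higher (the same counts adjusted over the list alone), such as H2-Q4 (−1.77 ± 0.14), H2-K1 (−1.17 ± 0.11) and H2-D1 (−0.91 ± 0.12). Extracellular matrix genes were higher for 14 of 18 members and lower for none (14 and 1 adjusted over the list alone), with the basal lamina collagens Col4a1 at 1.48 ± 0.14 and Col4a2 at 1.38 ± 0.13, Postn at 1.12 ± 0.11 and Nid1 at 1.02 ± 0.11.

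Of 19 NF-kB genes 8 were lower and 1 higher after PBS (7 and 1 adjusted over the list alone), Ier3 (−1.34 ± 0.18) and Nfkb2 (−1.25 ± 0.21) against Rel (1.43 ± 0.19), and of 27 interferon response genes 7 were lower and 4 higher (the same counts adjusted over the list alone), Irgm1 (−1.75 ± 0.14) and Irf1 (−1.10 ± 0.12) against Ifit2 (1.12 ± 0.18). Complement C4b was higher (3.04 ± 0.18) and so was Il6st (1.68 ± 0.16), and Cebpb (−1.59 ± 0.16) and Cebpd (−1.13 ± 0.12) were lower. Among repair genes Btc (2.87 ± 0.33) and Tnc (1.71 ± 0.21) were higher and Pou3f1 (−0.99 ± 0.13) lower, and the neurotrophic factor Cntf, with 2 untreated counts, was 172-fold (95% counting interval 47.4 to 1422) higher. That fold lay among those of the genes given below that an annotation can count differently. A difference in counting therefore stays open for Cntf. Of 7 cell cycle genes 5 were lower (5 adjusted over the list alone), Mki67 (−1.48 ± 0.20) and Pcna among them. Mt1 was lower (−1.48 ± 0.30), a call lost without untreated replicate 2 (adjusted p = 0.0538). The comparison called 5840 of 10583 genes, 2984 higher and 2856 lower, from profiles of 756260 to 4635994 UMIs, with 60.2% of the tested genes separated and 5589 calls with the replicate number as a block. The extreme fold changes fell on genes that an annotation can count differently: Rpl32, Usmg5, Ctage5 and Fbl were absent from the untreated profiles (at least 901-fold, at least 281-fold, at least 137-fold and at least 69.1-fold higher), Chchd2 had 1 untreated count (2900.2-fold (95% counting interval 520.4 to 114567)) and its pseudogene Chchd2-ps 3 PBS counts, and Mrpl53, Rnu1a1 and Zbed6 had no PBS count and Rpl17-ps8 had 2.

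The 2 Schwann-like classes were compared within the 3 untreated libraries, over the 174 tested members of the fixed lists, to see how they differ without a stimulus. Antigen presentation genes were higher in the non-myelinating class for 4 of 9 members (5 adjusted over the list alone): H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499), a class I heavy chain that shows peptides to T cells, was higher by 3.44 ± 0.33 on the log2 scale (SE, n = 3 libraries, library as a block), at 3475 ± 384 against 314 ± 58.2 CPM, and H2-K1 by 2.82 ± 0.47. H2-Q4, with 2 counts in the myelinating class, was 21.6-fold (95% counting interval 5.99 to 179) higher, and Psmb8, absent there, at least 4.40-fold. Of 20 interferon response genes 5 were higher (5 adjusted over the list alone), among them Gbp2, at least 3.75-fold. The stress genes Hspa1a (3.21 ± 0.35), Hspa1b (2.31 ± 0.39), Hspb1 (2.45 ± 0.57) and Atf3 (2.25 ± 0.25) and the transcription factor Cebpd (2.69 ± 0.30) were also higher in the non-myelinating class, with 4 of 12 heat shock genes higher (4 adjusted over the list alone). In the myelinating class, Pou3f1 (ENSMUSG00000090125, chromosome 4, 124656807 to 124660655), a transcription factor of the promyelinating stage also called Oct6, was higher, the difference being −3.08 ± 0.31 (269 ± 29.4 against 2294 ± 604 CPM in non-myelinating against myelinating cells). Sgk1 (−3.99 ± 0.38), Nr4a2 (−3.33 ± 0.34), Klf2 (−1.77 ± 0.33), Cdkn1a (−1.29 ± 0.26), Ndrg1 (−1.83 ± 0.33), Cryab (−1.24 ± 0.23) and the chemokine Cxcl14 (−6.94 ± 1.10) were higher there too. Cxcl14 had 7 and 13 myelinating counts in untreated replicates 1 and 2 and none in replicate 3, which went the other way (0 against 5.72 CPM).

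The untreated comparison of the classes called 47 of 174 list genes, 32 higher and 15 lower in the non-myelinating class, with 56.3% of the tested genes separated. The median log2 difference over the 174 genes was 0.647, and in simulated data unchanged genes shifted by a median of 0.15. TMM factors from all tested genes gave 71 calls, so the count and the balance of directions can depend on the scaling. Of 22 immediate early genes 6 were higher and 4 lower (9 and 4 adjusted over the list alone), of 10 glucocorticoid-responsive genes 5 were lower (5 adjusted over the list alone), and of 17 matrix genes 4 were higher (3 adjusted over the list alone), among them Postn, with 2 myelinating counts, 15.8-fold (95% counting interval 4.36 to 130.4). The myelinating profiles came from 4, 17 and 6 cells, with 10251 UMIs in the shallowest, and 18 of the 40 named calls were lost without at least 1 library, 14 of them without untreated replicate 2 (such as Cxcl12, adjusted p = 0.0784, Col6a1, 0.0805, and Mt1, 0.108) and 11 each without replicate 1 or 3. None of the genes given above with a value was lost so, but Cxcl14 could be tested without 1 of the 3 libraries alone. Without untreated replicate 2 the count was 27. With at least 1000 genes per cell it was 16, with 25 of 39 named calls lost.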

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

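The tests chosen only after the result was seen are the estimates of non-myelinating Schwann RNA and of neutrophil RNA behind the endothelial difference and their subtraction; the test of a difference between classes was planned.

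By the edgeR test the response to LPS differed between the 2 Schwann-like classes for 11 genes (n = 2 libraries per group). This is listed because the difference itself was tested, although no explanation for it was. Of the 11, 3 had the higher effect in myelinating and 8 in non-myelinating cells, where a fall in either class counts as a higher effect in the other. TMM factors from all tested genes gave 10 calls, 6 and 4, so the balance of directions depended on the scaling. Per gene the LPS effect in myelinating minus that in non-myelinating cells was −7.60 for Cxcl10, −3.21 for Gadd45b, −1.99 for Nfkbia, −1.75 for Klf4, −1.48 for Mt1 and −1.48 for Mt2. It was 2.45 for Cebpd and 3.22 for Fxyd6, a gene at 1467 and 1515 CPM in myelinating and 2.12 and 26.2 CPM in non-myelinating cells. With DESeq2 only Gadd45b (adjusted p = 0.0367) and Cxcl10 (1.40e-11) of these 8 genes passed. Calls other than Gadd45b were lost without particular libraries, Cxcl10 without PBS replicate 3 (adjusted p = 0.142) and Mt1 without LPS replicate 2 (0.0901), each from a fit with 1 library in an arm, which is assumed to vary like the others. With each cell thinned to 1000 UMIs none of the 8 passed, with Gadd45b at −2.41 (adjusted p = 0.910), Nfkbia at −2.32 (0.0517) and Mt1 at −1.46 (0.0682). Fxyd6 fell to 1.34 and Cebpd to 1.04, while Cxcl10 stood at −7.96, Klf4 at −1.57 and Mt2 at −1.56.

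The response to LPS also differed between endothelial-like and non-myelinating Schwann-like cells, with 375 genes past the test of the difference (n = 2 LPS and 3 PBS libraries). Here too a higher effect may reflect a fall in the other class. The effect was higher in non-myelinating cells for 17 of 33 interferon response genes and 6 of 13 antigen presentation genes, with differences of −3.02 for Iigp1, −2.01 for Igtp, −1.85 for Gbp2, −1.93 for H2-Q4, −1.28 for H2-K1, −1.38 for Psmb9 and −1.10 for Psmb8, and Ifit2 went the other way (2.66). The difference was −3.63 for Slfn5 and, among receptor genes, −1.11 for Ifngr2 and −1.04 for Tlr3. H2-K1 stood at 1927 CPM after LPS and 1927 after PBS in endothelial-like cells, and at 1322 and 528 in non-myelinating cells. Among NF-kB genes, chemokines and cytokines the differences were −7.75 for Il33, −2.67 for Cxcl16, −2.03 for Tnfaip2, −1.67 for Sod2, −1.63 for Nfkb1, −1.30 for Cxcl12 and −1.15 for Csf1, against 3.16 for Cxcl1 and 1.44 for Bcl3. Among host defence and receptor genes they were −5.69 for Ptx3, −4.16 for Lcn2 and −2.99 for Lrg1, against 3.03 for Cd14, 1.99 for Serpina3n and 1.38 for Cebpb. Stress and metabolic genes gave 3.52 for Mt1, 2.79 for Mt2, 2.86 for Pfkfb3, 2.37 for Hspa1b, 1.22 for Ndrg1, 1.11 for Atf3 and 1.05 for Dnajb1, against −1.89 for Vegfa and −1.27 for Sgk1. The remaining named genes gave 7.18 for Tnfaip6, 4.69 for G0s2, 3.92 for Cdh19, 3.74 for Retreg1 and 2.47 for Col5a3, against −3.39 for Plaur, −3.49 for Cyp26b1 and −3.62 for Lmo2. The direction turned for Ptx3 without PBS replicate 3 (0.38), for Cxcl1 (−0.41), Hspa1b (−0.57) and Ndrg1 (−0.00577) without LPS replicate 2, and for Col5a3 when thinned (−2.44). Of the 43 named genes 31 lost their call without at least 1 library, and the count was 125 without PBS replicate 3, 143 without LPS replicate 2, 209 without PBS replicate 2 and 211 without LPS replicate 3.

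A technical source of the higher endothelial-like effects may be RNA of other cells in endothelial droplets, either of non-myelinating Schwann-like cells, since Cdh19 and Col5a3, genes of Schwann cells, are among them, or of neutrophils, since the neutrophil marker G0s2 is. Schwann RNA, the median over 19 markers, was 2.88% and 0% of the endothelial-like LPS profiles and 0%, 0% and 0.639% of the PBS profiles. Neutrophil RNA, estimated from 9 markers, was 1.19% and 1.35% of the LPS profiles. Of the 197 genes with the higher endothelial-like effect, the 152 higher in both LPS libraries were used. Neutrophil RNA accounted for 0.994% of the rise of the median gene, which argues against it for this set. Schwann RNA accounted for 1.502% by the mean of the 2 libraries. In LPS replicate 2 it was 3.00%, which argues against it there. In LPS replicate 3 the estimate of 0% fixes every share at 0. Cdh19 still stood at 19.2 CPM there (29.5 in LPS replicate 2), so that library cannot decide. Schwann RNA reached at least 50% for 14 of the 152 genes, and neutrophil RNA, by the mean of the 2 libraries, for 9. Among these 9 were G0s2 (57.1% and 141%) and Cd14 (41.0% and 90.5%). The share of Schwann RNA in the rise of Cdh19 was 93.4% in LPS replicate 2 and 0% in LPS replicate 3. All these genes stay open. With Schwann RNA subtracted, 157 of the 197 genes with the higher endothelial-like effect were still called (for the 40 lost the median log2 difference went from 2.17 to 1.81 and its median SE from 0.56 to 1.03), and with neutrophil RNA subtracted 180 were (for the 16 lost 3.24 to 2.66 and 0.66 to 0.92), so the lost genes stay open too. A difference between the 2 cell types in how they respond to LPS stays open as the biological explanation.

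The untreated libraries held counts of the reporter transgenes, which no comparison used, and they are listed because the signal lies above what a count of 0 allows. The transgene feature tdTomato was detected in 19.5% (95% exact interval 17.4 to 21.7) of 1379 non-myelinating Schwann-like cells and the feature tWPRE in 99.1% (98.5 to 99.5), at a median of 3013, 2860 and 3586 UMIs per cell. Among 46 endothelial-like cells, which the sort should exclude, tdTomato was detected in 2.17% and tWPRE in 30.4% (17.7 to 45.8), at medians of 2837, 3158 and 685 UMIs. Pooled tWPRE stood at 4863 CPM in non-myelinating Schwann-like, 3635 in myelinating Schwann-like, 3284 in chondrocyte-like, 3198 in smooth muscle-like, 2234 in fibroblast-like and 143 CPM in endothelial-like cells. Single libraries did not keep this order. In untreated replicate 1 it was 3399 CPM in non-myelinating, 3189 in chondrocyte-like, 2053 in smooth muscle-like and 1973 in the 4 myelinating cells. In untreated replicate 3 it was 8375 CPM in the 3 smooth muscle-like cells and 6085 in non-myelinating cells.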

How the results depend on the processing

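The tests chosen only after the data were seen are the subtractions of neutrophil and of non-myelinating Schwann RNA, the fit without the shallow cluster, and TMM factors from all tested genes. Of 7803 values that 430 named results (a gene or a list in 1 comparison) took under the alternatives, 6856 kept direction and side of the threshold, 881 kept the direction but no longer passed, 34 passed only under the alternative and 32 changed sign. For class shares 250 of 264 kept their direction and 14 changed it.

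In non-myelinating Schwann-like cells the 1945 calls became 1229 with DESeq2, which shared 1117 of them. With each cell thinned to 1000 UMIs 821 genes passed. With untreated libraries as the baseline 5813 passed, and this contrast includes the PBS and annotation difference. Leaving out 1 library gave 1292 to 2002. With neutrophil RNA subtracted 1909 of the 1945 were kept. Camera with an estimated correlation called 0 lists.

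Counts in other comparisons moved as follows, and the cause was not tested. For the 1 call in myelinating cells, no filter gave 11, 250 genes per cell 4, 1000 genes per cell 6, 20% mitochondrial counts 4, doublets kept 12, thinning 6, 9 libraries in one fit 3, and leaving out 1 library 4 to 30. For the 306 endothelial-like calls, DESeq2 gave 188, no filter 532, thinning 75, the replicate block 146, and leaving out 1 library 129 to 460. For the 208 fibroblast-like calls, no filter gave 536, 1000 genes 322, 20% mitochondrial counts 429, resolution 0.5 430, thinning 25, and leaving out 1 library 89 to 313. For the 146 chondrocyte-like calls, the same settings gave 369, 235, 245, 239 and 18, and leaving out 1 library 45 to 257. For the 130 epithelial-like calls, DESeq2 gave 233, no filter 426, 250 genes 46, 1000 genes 2, thinning 19, the replicate block 77, and leaving out 1 library 24 to 140. Thinning gave 3366 calls for PBS against untreated. In the untreated comparison of classes (47), 1000 genes gave 16, TMM factors from all tested genes 71, and leaving out 1 library 27 to 35. For the myelinating difference (11), DESeq2 gave 2, no filter 7, thinning 0 (edgeR), and leaving out 1 library 5 to 21. For the endothelial difference (375), DESeq2 gave 85, 1000 genes 210, resolution 0.5 245, thinning 73, and leaving out 1 library 125 to 251.

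Changes of sign followed, and the cause was not tested. Against untreated libraries in the non-myelinating class the log2 change was −0.96 for Myc, −0.66 for Maff, −0.0556 for Sgk1, −0.42 for Atf4, −0.13 for Herpud1, −0.15 for Ldha, −0.23 for Vegfa, −0.62 for Insig1, 0.58 for Col5a3, 0.57 for Nid1, 0.60 for Postn, −0.25 for Mbp and 0.59 for Tlr4. Scn7a gave −0.0114 with DESeq2, −0.0181 without a filter, −0.0989 with upper-quartile scaling, −0.0642 with 1000 genes, −0.00673 with 20% mitochondrial counts and −0.102 when thinned. Without 1 library the range was −0.0433 to 0.0757 for Scn7a and −0.181 to 0.0427 for Tlr4. In the endothelial difference Col5a3 gave −2.44 when thinned, and without 1 library the range was −13.42 to 0.38 for Ptx3, −0.41 to 3.64 for Cxcl1, −0.57 to 3.06 for Hspa1b and −0.00577 to 2.93 for Ndrg1. Camera's adjusted p without 1 library ran from 0.488 to 0.973 for heat shock genes, 0.0270 to 0.920 for cholesterol synthesis and 0.252 to 0.973 for repair genes, which changed direction. In percentage points, LPS minus PBS ran from −1.31 to 0.342 for B cell-like, −2.27 to 0.275 for T or NK cell-like, −2.70 to 0.329 for fibroblast-like (0.0150 with doublets kept), −1.29 to 1.00 for macrophage-like and −0.753 to 12.4 for smooth muscle-like cells without 1 library. PBS minus untreated ran from −0.724 to 0.573 for smooth muscle-like cells. The replicate block could not be fitted for the myelinating class.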

Other observations

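The tests chosen only after the result was seen are the 2 tests on how neutrophil transcripts spread over the classes; the shares of the rise, the ratios between classes, the thinning and the splits were planned.

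Within the non-myelinating Schwann-like class, inflammatory transcripts were unevenly spread over the clusters, which had been built without the list genes. Other genes that LPS raised, such as Acod1 and Adamts4, were not left out, so the clusters were not independent of the LPS response. The levels below therefore describe the clusters and do not test whether cells differed in their response. Cluster 4 held 12.5%, 45.6% and 31.4% of the class in the LPS libraries and 0.178%, 2.65% and 3.06% in the PBS libraries. In LPS replicate 2 the pooled level of Ccl2, a monocyte attractant, was 8345 CPM in the 468 cells of cluster 4, against 434 and 674 CPM in the 257 and 240 cells of clusters 0 and 1. In the same 3 clusters Cxcl10 stood at 10072, 369 and 1789 CPM, Cxcl2 at 13691, 612 and 637, and the cytokine Lif at 266, 4.70 and 0. Ptx3 stood at 1225, 42.3 and 26.4 CPM, the protease inhibitor Timp1 at 2853, 108 and 134, and the neurotrophic factor Gdnf at 61.2, 5.29 and 0.755. The immediate early genes Fos (1861, 3944 and 8260 CPM) and Atf3 (800, 987 and 2239) had their lowest level in cluster 4.

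In LPS replicate 3, cluster 4 (195 cells) held Ccl2 at 5614 CPM against 465 and 591 in clusters 0 and 1, Cxcl10 at 9234 against 714 and 916, Lif at 151 against 8.16 and 1.83, and Nfkbia at 3092 against 1625 and 1572. Fos there stood at 2039 CPM against 3525 and 11462. In the 25 cells of cluster 4 in PBS replicate 3, Ccl2 stood at 262 CPM against 9.93 and 46.4, and Gdnf at 117 against 9.05 and 2.36. Ccl2 in clusters 0 and 1 of that PBS library lay below the same clusters of LPS replicates 2 and 3. These levels are pooled over cells of single libraries and were not tested.

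Neutrophil transcripts, the 2 most abundant being S100a8 and S100a9 (55211 and 73268 CPM in the neutrophil-like cells of LPS replicate 2), appeared in the non-myelinating Schwann-like cells of every LPS library, although the sort was set to exclude cells with the leukocyte protein CD45. Free neutrophil RNA at one level in every class is argued against, since its share in endothelial-like cells was 5.50-fold that in non-myelinating cells in LPS replicate 2 and 6.18-fold in LPS replicate 3. Neutrophil RNA in the droplets of other cells may be the source, since in LPS replicates 2 and 3, 8 of the 9 markers stood in 1 ratio to their level in neutrophil-like cells, within 3-fold of their median. The ninth, G0s2, was left out of this test because the class held it after PBS (414, 391 and 396 CPM), and it stood at 13.9-fold and 27.3-fold of that median. Neutrophil RNA is argued against as the source of the LPS response, since it accounted for 0.213% of the rise of the median of 1346 called genes and 0.145% for chemokines and cytokines, and for at least 50% in 28 genes.

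The difference between PBS and untreated non-myelinating Schwann-like cells may be one of library run or annotation, and it extends to other cells. For 73 genes more than 8-fold apart, the log2 ratio in endothelial-like cells was 1.01 of that in non-myelinating cells at the median (quartiles 0.859 to 1.17), and for 2103 called genes up to 8-fold apart it was 0.839 (0.397 to 1.31), as a factor common to both classes needs. A difference in depth is argued against as the whole source, since 70.2% of the calls still tested (3250 of 4628) were called in the same direction with each cell thinned to 1000 UMIs. A response of every class to the aspiration would give the same ratios and stays open, because treatment is confounded with annotation.

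Other splits of the 6 libraries into 3 and 3 were counted for 5 comparisons, and 1 of the 10 splits, the real one, called as many genes in each. The real and the highest other count were 1945 and 0 for non-myelinating Schwann-like, 208 and 1 for fibroblast-like, 146 and 1 for chondrocyte-like and 130 and 0 for epithelial-like cells, and 5840 and 0 for PBS against untreated. The splits are too few for a share under 0.05.

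Erdr1 was lower after LPS by the edgeR test in endothelial-like, fibroblast-like and chondrocyte-like cells, the fibroblast-like call (log2 change −4.31, adjusted p = 0.0419) being lost without any 1 of the 6 libraries (adjusted p from 0.0672 to 0.114) and the endothelial-like call without LPS replicate 2 (0.0983). In non-myelinating Schwann-like cells Erdr1 did not pass (−3.36, adjusted p = 0.0902), at 339, 137 and 208 CPM after PBS and 51.9, 4.85 and 35.1 CPM after LPS. Of the non-myelinating cells of LPS replicate 1, 51.7% lay in the shallow cluster 8, which held at most 5.94% of the class in any other library.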
